A study of Mus musculus with 10 samples.

How the data were processed

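Gene expression was measured in 10 samples of normal mouse thymus in 4 groups. The groups were p53-null with wild-type mdm2 (n = 3), mutant p53 with wild-type mdm2 (n = 3), p53-null with mdm2 null (n = 2) and mutant p53 with mdm2 null (n = 2). The mutant p53 allele carries the number 246 in the labels. Per the labels, the mice were C57BL6/129 hybrids aged 4 to 5 weeks, and sex was not given. Replicate numbers come from the sample titles, and the labels do not say more about whether replicates were separate animals. No sample had wild-type p53.

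Per the labels' protocols, RNA was extracted with Trizol and purified on RNeasy columns, ribosomal RNA was reduced, and cDNA was amplified, fragmented and labelled with biotin using Affymetrix whole-transcript kits. Processing was in Partek 6.5 with genome build mm8, per the submitters' processing notes. The series' design text, per the labels, names a mixed-model analysis of variance in Partek without its factors. The deposited values are processed log2 signals. The range of the values, with medians from 6.1 to 6.26 per sample, fits a log2 scale. The normalization and the summary of probes into features were not stated. The deposited values were used as they stand, and none of the columns of values was left out.

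The table held 23332 features per sample. The platform annotation gave 1 gene symbol to 14996 features, several to 1019 and none to 7317. Features with 1 symbol covered 14860 genes, and 135 genes had more than 1 such feature. Of the features with 1 symbol, 14941 had an identifier present in the gene table of assembly GRCm38.p6 and 55 did not. As that assembly differs from the build of the submitters, it served only for names, gene lengths and the order of neighbouring genes, and no coordinates are given. A feature with several symbols or none was tested and counted but gave a gene no value.

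All 23332 features were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 on the adjusted p. A feature under that threshold is called. Comparisons between 2 groups and the difference of the p53 effect between mdm2 backgrounds came from a model with 1 mean per group, fitted to all 10 samples. The p53 and mdm2 effects over both backgrounds came from an additive model of the 2 genotypes. The models left 6 and 7 residual degrees of freedom, and moderation added 2.85 and 2.81. The p-values of features measure spread between samples of a group. The number of arrays limits the precision, and the median SE of a log2 change ranged from 0.123 to 0.25 across comparisons.

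The choice of comparisons, tests, gene lists and most alternatives was made before the data were examined. The 24 gene lists held 502 members, of which 382 were measured, and 21 lists had at least 4 measured members from which a shift could be tested. Shifts were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 21 lists. At that preset members of a list count as almost independent, so the p-value mostly measures spread across genes, not between samples. Camera with an estimated correlation and the rotation test fry, which allow for members that vary together, were run as alternatives. Both called 0 lists in each comparison. For the same reason the number of members with 1 sign is not independent support. A list of liver genes and a list of genes restricted to other organs were added after the data had been seen. Trp53, Xist, Ddx3y and Uty had no named feature and were not analysed here. A sex score was therefore the mean of Kdm5d and Eif2s3y. It was 3.59 in p53-null, mdm2 wild-type replicate 1 and 8.49 to 9.35 in all other samples. As a covariate it thus mostly marks that 1 sample.

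Genes were named by a fixed rule from features with 1 symbol. Mdm2 and Cdkn1a were named in each comparison. Up to 10 of the largest rises and 10 of the largest falls were named among called genes whose groups did not overlap. Where fewer than 10 passed, genes with the smallest unadjusted p were added up to 10 and are given as not passing. The 4 members of smallest p were named for the p53 target list and for each list called by camera. Where a gene had several features, the one with the highest mean was used. Any gene outside the rule is given as chosen after its values were seen.

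The tests were tested on simulated data with 200 of 23332 features changed and noise drawn independently for each feature and sample. Samples that deviate in many features at once were not simulated, so the shares below need not hold for the real samples. For the mdm2 effect over both p53 genotypes, 39% of features changed 1.5-fold, 74% changed 2-fold and 97% changed 4-fold were recovered. For the p53 effect over both mdm2 backgrounds the shares were 44.5%, 74% and 96.5%. Recovery of 1.5-fold and 2-fold changes was 0% and 63% for the p53 effect with wild-type mdm2, and 0% and 32% for the p53 effect with mdm2 null. Recovery of 2-fold changes was 56% for the mdm2 effect in p53-null thymi and 47% in mutant p53 thymi.

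Alternatives were quantile normalization, median centring, leaving out dim features, 1 feature per gene, eBayes with trend and robust settings, a plain linear model without moderation, array weights, the sex score as a covariate, sex chromosome genes left out, other thresholds, fits to only the 2 groups compared, a block for replicate number and leaving out each sample in turn. A liver score as a covariate, liver genes left out of the counts and an averaged contrast of the group-means model were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.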

Results

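Thymic expression was compared between mice without p53 and mice with the mutant p53 allele, each with or without mdm2. Signals were available for 23332 features in each of 10 samples, and sample medians lay between 6.1 and 6.26 on the log2 scale. Correlation between samples across features ranged from 0.967 to 0.991, with a median of 0.984 within groups and 0.978 between groups. No pair of samples had identical columns. The first principal component held 28.4% of the variance and separated all 4 mdm2-null samples from all 6 mdm2 wild-type samples. The second held 17.7%. The array names fell into 3 sets by prefix, and 0 of these held samples of both mdm2 genotypes, so that the mdm2 comparisons and the array set cannot be told apart. The mdm2-null groups also differed from each other in prefix, whereas both mdm2 wild-type groups shared 1. The p53 comparison without mdm2, and with it the difference of the p53 effect between mdm2 backgrounds, can therefore not be told apart from the array set either.

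Mdm2, which encodes the ubiquitin ligase that marks p53 for degradation, was lower in each mdm2-null sample than in any mdm2 wild-type sample. With wild-type mdm2 its log2 signal averaged 9.51 ± 0.06 (SD, n = 3) in p53-null thymi and 9.60 ± 0.02 (SD, n = 3) in mutant p53 thymi. Without mdm2 it averaged 8.34 ± 0.09 (SD, n = 2) and 8.39 ± 0.06 (SD, n = 2). Over both p53 genotypes Mdm2 fell by 1.19 on the log2 scale (SE 0.07, adjusted p = 9.24e-05 by limma with Benjamini-Hochberg adjustment), a 2.28-fold difference in the direction of the labels in all 10 samples. The part of the gene removed in the null allele is not stated, and the Mdm2 feature (6777346) may not lie within it. Mdm2 differed by 0.09 (SE 0.09, adjusted p = 1) between p53 genotypes with wild-type mdm2 and by 0.06 (SE 0.11, adjusted p = 1) without it. The p53 genotype was not checked in this way, as Trp53 was not analysed here.

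**Figure D1:**
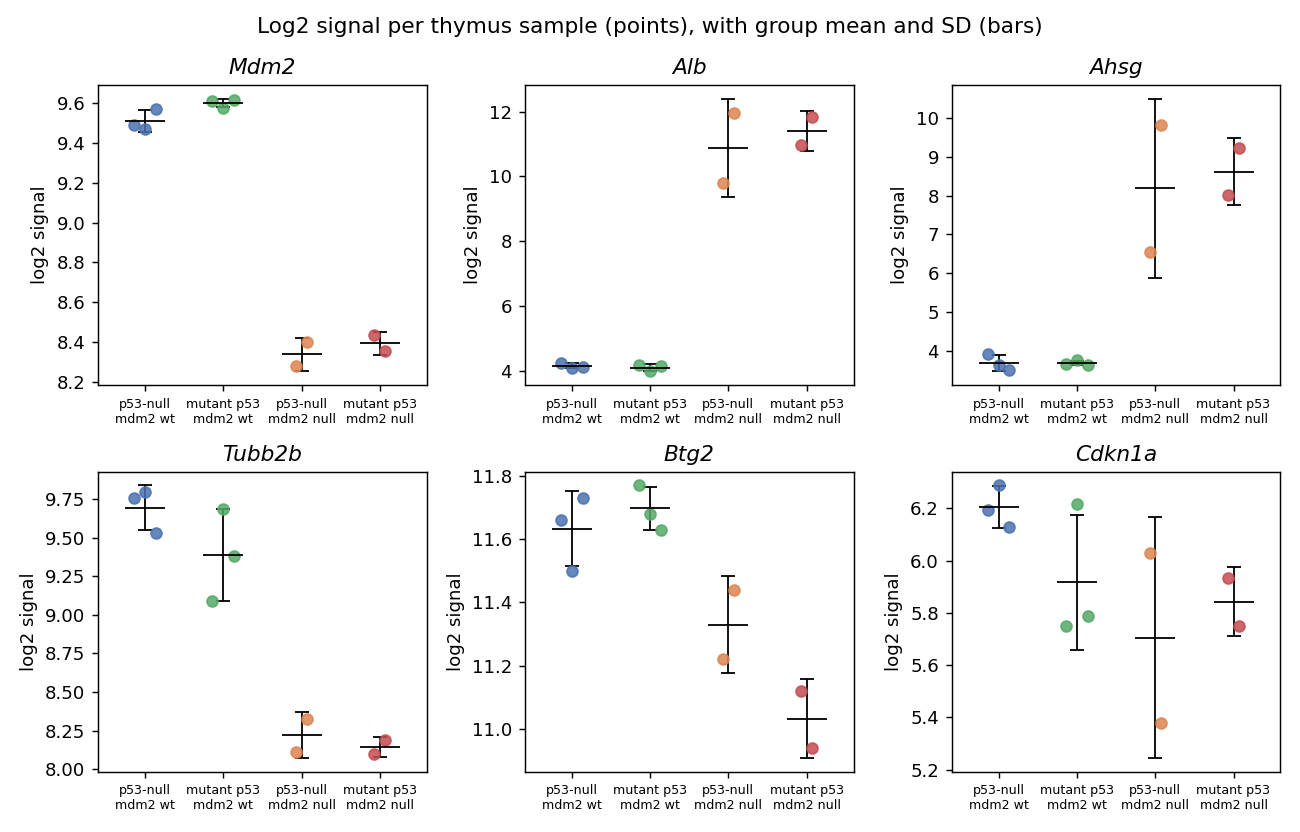
Log2 signal of 6 genes in each of the 10 thymus samples, with 1 point per sample and bars for the mean and SD of each group (n = 3, 3, 2 and 2 from left to right). Mdm2 and Tubb2b were lower and Alb and Ahsg higher in all 4 mdm2-null samples than in all 6 mdm2 wild-type samples.

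The effect of mdm2 loss over both p53 genotypes asked which transcripts follow mdm2 when p53 is absent or mutant. Transcripts of proteins that the liver secretes made up most of the largest rises. Alb, the gene for serum albumin, rose from 4.13 ± 0.08 (SD, n = 6) to 11.1 ± 0.99 (SD, n = 4), a log2 change of at least 7.01 (SE 0.36, adjusted p = 3.99e-05, limma with Benjamini-Hochberg adjustment). Ahsg, which encodes fetuin-A, rose by 4.71 (SE 0.52, adjusted p = 0.0071) and Ttr, which encodes the thyroid hormone carrier transthyretin, rose by 4.00 (SE 0.49, adjusted p = 0.00884). The heme carrier gene Hpx rose by 3.82 (SE 0.53, adjusted p = 0.0138) and the retinol carrier gene Rbp4 by 3.23 (SE 0.42, adjusted p = 0.0108). Apoa2 rose by 3.43, Uox by 3.10, Apoh by 3.07, Fgg by 3.03 and Fgb by 3.03, with adjusted p between 0.0181 and 0.0322. For these 10 genes each mdm2-null sample was above each mdm2 wild-type sample, as the naming rule required. With mdm2, the mean signals of Alb, Ahsg, Rbp4, Uox, Apoh, Fgg and Fgb lay under the lower quartile of all features in each sample (4.3 to 4.45), and without detection calls their changes are lower bounds. The excess was uneven: Alb reached 9.81 in p53-null, mdm2-null replicate 1 and 11.96 in replicate 2 of that group.

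Among the largest falls over both p53 genotypes, Rgs5, a marker of pericytes, fell by 1.41 (SE 0.20, adjusted p = 0.0138, limma with Benjamini-Hochberg adjustment) and the tubulin gene Tubb2b fell by 1.36 (SE 0.13, adjusted p = 0.00341). Scg5, which encodes a chaperone of secretory granules, fell by 1.28 (SE 0.19, adjusted p = 0.014), and the transcriptional repressor gene Trps1 fell by 0.97 (SE 0.12, adjusted p = 0.00823). The prostaglandin synthase gene Ptgs2 fell by 1.22, Rgs4 by 0.95, Epsti1 by 0.93, the casein gene Csn2 by 0.90 and the angiopoietin gene Angpt1 by 0.88, with adjusted p between 0.0222 and 0.0439. Each mdm2-null sample was below each mdm2 wild-type sample for these genes, as the naming rule required.

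In all, limma called 902 features, 458 higher and 444 lower without mdm2, out of 4909 at an unadjusted p under 0.05, where chance gives 1167. They included 546 genes with a single symbol, and 461 features changed at least 1.5-fold. Median centring gave 539 higher and 277 lower, quantile normalization 610 and 485, and leaving out the dimmer 50% of features 576 and 724. The plain linear model called 453. With the liver score as a covariate, a setting chosen after seeing the data, 8 were called. That score was 4.88 to 6.91 in mdm2-null and 4.02 to 4.26 in mdm2 wild-type thymi, without overlap. The covariate can therefore hardly be told apart from mdm2 genotype, and the drop does not show that liver signal explains the calls. Without mutant p53, mdm2-null replicate 1 or 2 the count was 408 or 114, and without p53-null, mdm2-null replicate 2 it was 382. It was 519, 298 or 273 without p53-null, mdm2 wild-type replicate 1, 2 or 3, and 153, 491 or 156 without mutant p53, mdm2 wild-type replicate 1, 2 or 3. Leaving out p53-null, mdm2-null replicate 1 gave 776.

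Of the 29 calls on named genes over both p53 genotypes, 11 held in each fit that left out 1 sample. These were Mdm2, Alb, Ahsg, Ttr, Hpx, Rbp4, Rgs5, Tubb2b, Scg5, Trps1 and Ccr4. The other 18, such as Apoa2 (adjusted p = 0.0606), Apoh (0.0581) and Ptgs2 (0.105), were all lost without mutant p53, mdm2-null replicate 2 by limma with Benjamini-Hochberg adjustment. Fewer were lost without the other samples. The numbers lost were 8 without mutant p53, mdm2-null replicate 1, and 7 or 10 without p53-null, mdm2-null replicate 1 or 2. They were 16, 11 or 17 without mutant p53, mdm2 wild-type replicate 1, 2 or 3, and 10, 9 or 14 without p53-null, mdm2 wild-type replicate 1, 2 or 3.

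Adipocyte genes as a list were higher without mdm2. The glucose transporter gene Slc2a4 rose by 1.0 (SE 0.20, adjusted p = 0.0317, limma with Benjamini-Hochberg adjustment), Pck1 by 1.52 (SE 0.32, adjusted p = 0.0365) and Cidea by 2.18 (SE 0.50, adjusted p = 0.0455). Ucp1, the uncoupling protein of brown fat, was 5.27 ± 0.85 (SD, n = 6) and 7.93 ± 1.66 (SD, n = 4), which did not pass (adjusted p = 0.068). All 15 measured adipocyte genes had a positive change, with a median of 0.85, and 3 were called over all genes and 6 adjusted over the list alone. The list was called by camera (adjusted p = 3.72e-06, limma), but not so with adjusted p = 0.867 with an estimated correlation. The call on the list held without any 1 sample, although its mean overlapped between mdm2 genotypes. It was 6.61 in p53-null, mdm2 wild-type replicate 1, above 5.94 in mutant p53, mdm2-null replicate 1 and 6.41 in p53-null, mdm2-null replicate 2. The gene calls were lost in 8 of 10 fits that left out 1 sample for Slc2a4, 8 for Pck1 and 9 for Cidea, at adjusted p of up to 0.0923, 0.103 and 0.0984, each without mutant p53, mdm2-null replicate 2.

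Some genes of mitosis and of thymocytes were lower without mdm2 by small amounts. The mitotic kinesin genes Kif20a, Kif11 and Cenpe fell by 0.42, 0.34 and 0.57 (adjusted p = 0.0409, 0.0422 and 0.0435, limma with Benjamini-Hochberg adjustment), and Nusap1 differed by -0.61 (adjusted p = 0.0581). Kif20a lost its call in 9 of 10 fits that left out 1 sample, and Kif11 and Cenpe lost theirs in all 10. Among genes of double positive thymocytes, Ccr4 fell by 0.59 (SE 0.09, adjusted p = 0.014) from 3.71 to 3.12, near the low end of the signal, and the recombinase gene Rag2 was 9.19 ± 0.11 (SD, n = 6) and 8.58 ± 0.37 (SD, n = 4; adjusted p = 0.0528). Themis differed by -0.24 and Cplx2 by 0.19, which did not pass. Of the antigen receptor signalling genes Ikzf2, which encodes Helios, fell by 0.65 (adjusted p = 0.0495), whereas Pdcd1 at -0.61, Nr4a2 at -0.43 and Egr1 at 0.33 did not pass. The call on Ikzf2 was lost in 9 of 10 fits that left out 1 sample. The interferon-induced genes Rtp4, Ddx58, Ifih1 and Oas2 differed by -0.47, -0.34, -0.33 and -0.53 without passing.

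By camera, 4 lists were shifted down without mdm2, although in each the means of single samples overlapped between mdm2 genotypes. The G2 and M phase list held 27 genes with a median of -0.13 (adjusted p = 0.00223, limma; adjusted p = 0.867 with an estimated correlation). The double positive thymocyte list (15 genes, median -0.15, adjusted p = 0.00741), the interferon response list (16 genes, median -0.22, adjusted p = 0.00741) and the list of TCR signalling and selection (17 genes, median -0.19, adjusted p = 0.0409) were shifted down as well, each with adjusted p = 0.867 with an estimated correlation. Over all genes 3, 1, 0 and 1 members of these lists were called, and 4, 2, 0 and 3 adjusted over the list alone. The interferon mean was 7.47 and 7.59 in replicate 1 of the mutant p53 and p53-null groups without mdm2, within the range of 7.42 to 7.66 with mdm2. Without mutant p53, mdm2-null replicate 2 the list calls on G2 and M phase (adjusted p = 0.0696), interferon response (0.0771) and TCR signalling and selection (0.321) were lost. Without p53-null, mdm2-null replicate 2 those on interferon response (0.106) and TCR signalling and selection (0.0726) were lost, and the latter was also lost without mutant p53, mdm2 wild-type replicate 2 (0.153) or p53-null, mdm2 wild-type replicate 2 (0.13). The call on double positive thymocytes held without any 1 sample. Without the dimmer 25% of features it was lost (0.0749), as was TCR signalling and selection (0.0749), which quantile normalization also ended (0.0663).

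With the liver score as a covariate, a setting chosen after seeing the data, limma's camera no longer called G2 and M phase (adjusted p = 0.115) or TCR signalling and selection (0.379, turned upward). The interferon response list was then called in the opposite direction, as higher without mdm2 (0.00221). The calls on double positive thymocytes (4.19e-05) and adipocytes (0.000178) kept their direction. As the liver score did not overlap between mdm2 genotypes, neither the losses nor the reversal can be ascribed to liver signal.

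Transcripts that p53 activates showed no shared shift with mdm2 loss. Among the 32 measured p53 target genes, the antiproliferative gene Btg2 fell by 0.48 (SE 0.10, adjusted p = 0.0384, limma with Benjamini-Hochberg adjustment), from 11.7 to 11.2. The cell cycle inhibitor gene Cdkn1a was 6.06 ± 0.23 (SD, n = 6) and 5.77 ± 0.29 (SD, n = 4), which did not pass (adjusted p = 0.341). The proapoptotic gene Pmaip1 differed by -0.51 (adjusted p = 0.0677), Sesn2 by -0.41 and Ddit4l by 0.63, none of which passed. The median of the list was -0.03 (camera adjusted p = 0.667), with 1 member called over all genes and 1 adjusted over the list alone. The call on Btg2 was lost in 8 of 10 fits that left out 1 sample. Its adjusted p was 0.0786 or 0.108 without mutant p53, mdm2-null replicate 1 or 2, and 0.0676 without p53-null, mdm2-null replicate 1. It was 0.0869, 0.0672 or 0.0827 without mutant p53, mdm2 wild-type replicate 1, 2 or 3, and 0.056 or 0.0736 without p53-null, mdm2 wild-type replicate 1 or 3.

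In the other lists camera made no call on mdm2 loss over both p53 genotypes. The median log2 change was -0.10 in the list of G1/S and DNA replication, -0.05 in replication-dependent histones, -0.04 in apoptosis regulators and -0.04 in early thymocytes. Only 4 of the 22 listed histone genes were measured. Outside the naming rule, features shared by several histone genes were called in both directions by limma with Benjamini-Hochberg adjustment. A feature of H4 genes changed by -1.04 (SE 0.17, adjusted p = 0.0222) and one of H2a genes by 0.96 (SE 0.15, adjusted p = 0.0181). It was -0.10 in mature single positive thymocytes, 0.05 in the Notch and Myc programme, -0.03 in immediate early and heat shock genes and -0.10 in the glucocorticoid response. Medians in cell type lists were 0.03 in thymic epithelium, -0.14 in B cells and plasma cells, -0.08 in macrophages and dendritic cells and 0.05 in granulocytes and mast cells. They were 0.37 in erythroid cells, 0.08 in fibroblasts and vessels and 0.14 in skeletal muscle. The feature shared by Hbb-b1 and Hbb-b2, which counted in no list and was chosen after its values were seen, rose by 2.62 (SE 0.45, adjusted p = 0.0232, limma with Benjamini-Hochberg adjustment). The mean had the opposite sign to the median in histones (0.05) and in granulocytes and mast cells (-0.01), and camera's direction was down in thymic epithelium. In the Notch and Myc programme 1 gene was called over all genes and 5 adjusted over the list alone, and in histones 0 and 1. In each of the remaining lists both counts were equal, between 0 and 2.

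In p53-null thymi, Alb and a feature for the angiotensin receptor-associated gene Agtrap were higher without mdm2. Agtrap rose from 6.83 ± 0.03 (SD, n = 3) to 8.47 ± 0.04 (SD, n = 2; log2 change 1.64, SE 0.10, adjusted p = 0.00191, limma with Benjamini-Hochberg adjustment). Alb rose by at least 6.72 (SE 0.52, adjusted p = 0.00345) and Mdm2 fell by 1.17 (SE 0.10, adjusted p = 0.00876). Outside the naming rule, a feature shared by the beta-globin genes Hbb-b1 and Hbb-b2 rose by 3.78 (SE 0.38, adjusted p = 0.0213) and 1 without a symbol by 1.82 (SE 0.14, adjusted p = 0.00345). The tubulin gene Tubb2b at -1.47 (adjusted p = 0.0747), the heme synthesis gene Alas2 at 1.75 (0.102), Arsb at 1.16 (0.102), Aldh1a1 at 1.64 (0.102), Ldlrad3 at -0.76 (0.111), Rab27a at 0.77 (0.149) and Ccr4 at -0.71 (0.149) did not pass, and the 2 features of Arsb went in opposite directions. Of the p53 targets Cdkn1a differed by -0.50 (adjusted p = 0.447), Pmaip1 by -0.57, Btg2 by -0.30 and Zmat3 by 0.34, with 0 called over all genes and 0 adjusted over the list alone. The 5 calls were 4 higher and 1 lower, and 2506 features had an unadjusted p under 0.05, where chance gives 1167. The plain linear model called 4, a limma fit to the 2 groups alone 0, a fit with the liver covariate 2, and limma without the dimmer 50% of features 13. Mdm2 lost its call in the fit to 2 groups (adjusted p = 0.223) and with the liver covariate (0.137), and its adjusted p ranged from 0.00183 to 0.223 over all alternatives. The count was 3 without p53-null, mdm2 wild-type replicate 2, where Mdm2 lost its call (adjusted p = 0.065), and 62 or 10 without p53-null, mdm2-null replicate 1 or 2.

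Lists of adipocyte and erythroid genes were shifted up and that of macrophage genes down in p53-null thymi without mdm2. Groups overlapped in each list, and the list calls rested on single samples. The feature shared by Hbb-b1 and Hbb-b2, which counted in no list, was 7.898 ± 0.685 (SD, n = 3) and 11.676 ± 0.367 (SD, n = 2), so its rise did not rest on 1 mdm2-null sample. Ucp1 was 5.26 ± 1.27 (SD, n = 3) and 8.30 ± 1.51 (SD, n = 2), and Cidea, Pck1 and Slc2a4 differed by 2.29, 1.85 and 0.69. The list of 15 adipocyte genes had a median of 0.66 (camera adjusted p = 0.000222, limma; adjusted p = 1 with an estimated correlation). Among 11 erythroid genes, Slc4a1 differed by 1.61, Car2 by 1.29 and the transferrin receptor gene Tfrc by -0.50, and the median was 0.65 (adjusted p = 0.00133; adjusted p = 1 with an estimated correlation). Without p53-null, mdm2-null replicate 1 both calls were lost, with adjusted p of 0.366 for adipocytes and 0.807 for erythroid cells. Among 19 macrophage and dendritic cell genes Ccl22 differed by -0.63, Fcgr3 by -0.77, and the complement genes C1qb and C1qc by -0.50 and -0.41. The median was -0.31 (adjusted p = 0.00847; adjusted p = 1 with an estimated correlation), and the call was lost without p53-null, mdm2-null replicate 2 (0.319) or p53-null, mdm2 wild-type replicate 2 (0.352). With the liver covariate it was lost and turned upward (0.422), and the erythroid call was lost without the dimmer 25% of features (0.0779). In each of the 3 lists 0 genes were called over all genes, and 1, 1 and 0 adjusted over the list alone.

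In mutant p53 thymi the same genes led the mdm2 comparison. Alb rose from 4.10 ± 0.10 (SD, n = 3) to 11.4 ± 0.62 (SD, n = 2; log2 change at least 7.30, SE 0.52, adjusted p = 0.00257, limma with Benjamini-Hochberg adjustment). Agtrap rose by 1.63 (SE 0.10, adjusted p = 0.00203) and Mdm2 fell by 1.21 (SE 0.10, adjusted p = 0.00907). Arsb at 1.34 (adjusted p = 0.0509), the metabolic regulator gene Klf15 at 0.88 (0.0553), and Ldlrad3 at -0.83, Ing3 at -0.78, Lysmd3 at -1.15, Tubb2b at -1.24 and Usp48 at 1.01 (0.0628 each) did not pass, and the 2 features of Usp48 went in opposite directions. Cdkn1a differed by -0.08 (adjusted p = 0.914). Btg2 at -0.66 (0.0897) and Ddit4l at 1.07 (0.117) were the 2 p53 targets called adjusted over the list alone, with 0 over all genes, and Sesn2 differed by -0.62 and Trp53inp1 by -0.41. The 3 calls were 2 higher and 1 lower, and 3823 features had an unadjusted p under 0.05, where chance gives 1167. The plain linear model called 4, limma with quantile normalization or the Y-linked covariate 7 each, with array weights 13, with 1 feature per gene 25, with trend and robust settings 26, and without the dimmer 25% or 50% of features 11 or 143. A fit to the 2 groups alone called 8 and one with the liver covariate 1. Mdm2 lost its call in both (adjusted p = 0.0953 and 0.145), and its adjusted p ranged from 0.00138 to 0.145 over all alternatives.

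Single samples decided much of this count. It was 0 without mutant p53, mdm2-null replicate 2, where Alb and Agtrap reached adjusted p = 0.0538 and Mdm2 0.0689 by limma with Benjamini-Hochberg adjustment. It was 63 without p53-null, mdm2-null replicate 1 or 2 and 7 without p53-null, mdm2 wild-type replicate 1. The call on Mdm2 was also lost without mutant p53, mdm2-null replicate 1 (0.0528) and without mutant p53, mdm2 wild-type replicate 1 (0.062), 2 (0.0582) or 3 (0.0878). The effects of mdm2 loss in the 2 p53 genotypes correlated across features (Pearson r = 0.492, same sign in 63.5% of 23332 features). Without the 48 measured genes of the liver list r was 0.451, but other genes that liver expresses, such as Hp and Orm1, stayed in. The agreement was thus not shown to be free of liver signal. Over all features r was 0.318 without mutant p53, mdm2-null replicate 2. Features are not independent replicates.

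Thymocyte and adipocyte genes also differed with mdm2 in mutant p53 thymi. Slc2a4 was 5.49 ± 0.15 (SD, n = 3) and 6.80 ± 0.10 (SD, n = 2), and Cidea, Pck1 and Lpl differed by 2.07, 1.20 and 0.79. The adipocyte list had a median of 1.06 (camera adjusted p = 4.3e-05, limma; adjusted p = 0.726 with an estimated correlation). Among double positive thymocyte genes the coreceptor gene Cd4 differed by -0.41, Rag2 by -0.70, Ccr4 by -0.46 and Ets2 by -0.39, with a list median of -0.28 (adjusted p = 0.00162; adjusted p = 0.726 with an estimated correlation). The G2 and M phase list, with Kif2c at -0.54, Nusap1 at -0.72, Kif20a at -0.45 and Kif11 at -0.36, had a median of -0.21 (adjusted p = 0.000598; adjusted p = 0.726 with an estimated correlation). The list of TCR signalling and selection had a median of -0.27 (adjusted p = 0.00602; adjusted p = 0.726 with an estimated correlation), with Pdcd1 at -0.93, Nr4a2 and Ikzf2 at -0.71 and Egr2 at -0.57. The interferon list had a median of -0.21 (adjusted p = 0.0109; adjusted p = 0.726 with an estimated correlation), with Oas2 at -0.78, Rtp4 at -0.53, Ifit1 at -0.44 and Ddx58 at -0.30. Mature single positive thymocytes, with Gimap6 at -0.61, Cd40lg at -0.78, Slfn1 at -0.64 and Gimap4 at -0.52, had a median of -0.20 and skeletal muscle, with Tnni2 at 0.70, Mb at 0.71, Pvalb at 0.59 and Mylpf at 0.45, one of 0.17 (adjusted p = 0.0417 for both; adjusted p = 0.726 with an estimated correlation).

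Of these 7 lists in mutant p53 thymi, only double positive thymocytes kept its call without any 1 sample. Without mutant p53, mdm2-null replicate 2 the limma camera calls on adipocytes, TCR signalling and selection, interferon response and mature single positive thymocytes were lost at adjusted p = 0.375, G2 and M phase at 0.313 and skeletal muscle at 0.727. Without mutant p53, mdm2 wild-type replicate 2, TCR signalling and selection and mature single positive thymocytes were lost at 0.0676. The latter was also lost without replicate 3 of that group (0.0807) or p53-null, mdm2 wild-type replicate 2 (0.0537), and skeletal muscle without mutant p53, mdm2 wild-type replicate 1 (0.0799) or 3 (0.0625). Mature single positive thymocytes and skeletal muscle were also lost with quantile normalization (0.0626 each) and without the dimmer 25% of features (0.0875 each), and the former with the Y-linked covariate (0.0535). With the liver covariate, chosen after seeing the data, TCR signalling and selection (0.891), skeletal muscle (0.484) and mature single positive thymocytes (0.161, turned upward) were lost, and interferon response was called as higher without mdm2 (0.0262). Over all genes 0 members of these lists were called. Adjusted over the list alone, 1 adipocyte, 1 double positive, 1 mature single positive and 2 TCR signalling genes were called, and 0 in the other 3 lists.

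**Figure D2:**
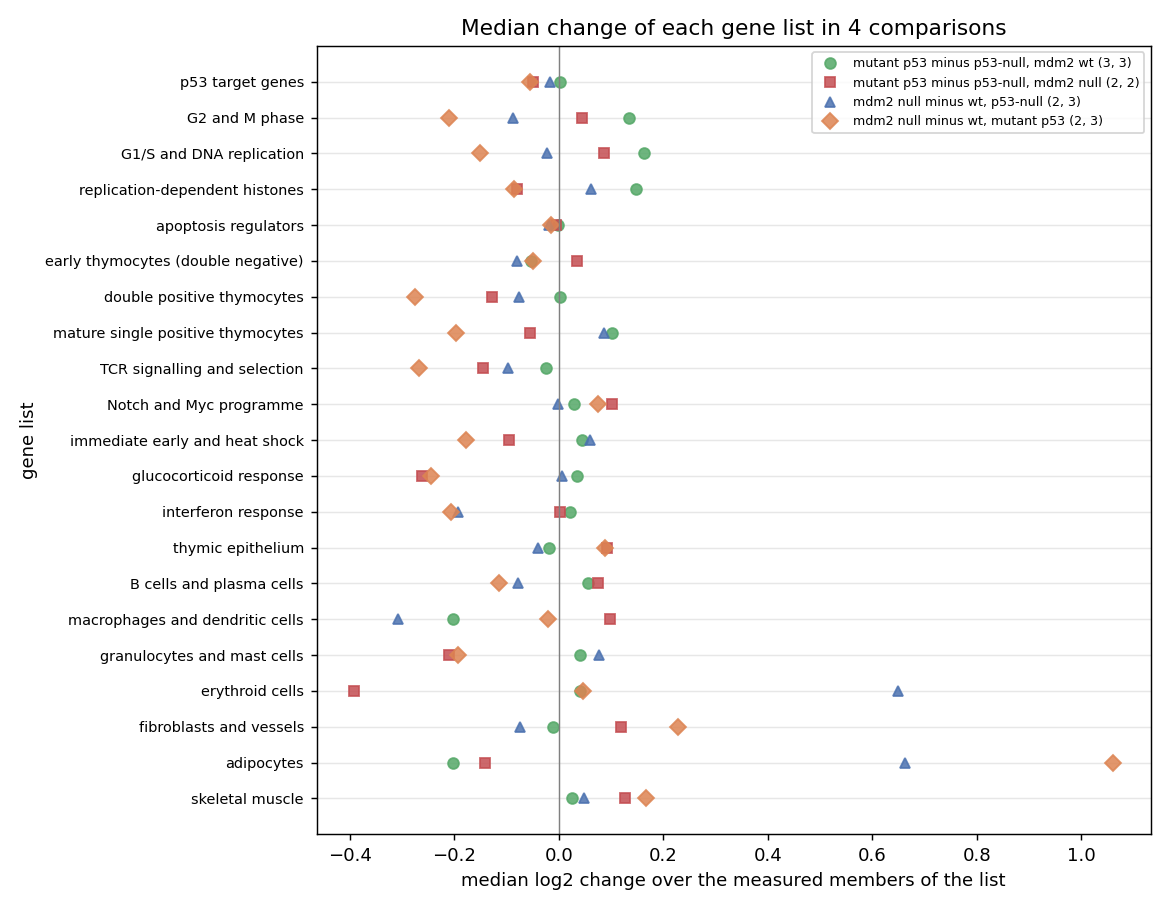
Median log2 change (x axis) of each of 21 gene lists (y axis) for mutant p53 against p53-null in each mdm2 background and for mdm2 null against wild type in each p53 genotype, with the number of samples per group in brackets. Adipocyte genes lay at 0.66 and 1.06 for mdm2 loss, and G1/S genes at 0.16 for mutant p53 with wild-type mdm2.

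Mutant p53 was compared with p53 loss, with mdm2 present, to ask what the mutant protein adds. Genes of DNA replication and mitosis were shifted up slightly with the mutant, with overlap between groups. The replication gene Fen1 was 8.76 ± 0.23 (SD, n = 3) in p53-null and 9.13 ± 0.02 (SD, n = 3) in mutant p53 thymi, and Tk1, Pola1 and Rfc4 differed by 0.63, 0.23 and 0.28. Positive changes were seen in 25 of 26 genes of G1/S and DNA replication, with a median of 0.16 (camera adjusted p = 2.27e-07, limma; adjusted p = 0.978 with an estimated correlation). They were seen in 26 of 27 genes of G2 and M phase, with a median of 0.14 (adjusted p = 1.15e-06; adjusted p = 0.978 with an estimated correlation), including Ndc80 at 0.44, Cdc20 at 0.34, Prc1 at 0.28 and Plk1 at 0.22. Both calls held without any 1 sample. The G1/S mean of 9.08 in p53-null replicate 3 lay above 9.06 in mutant p53 replicate 3, and its G2 and M mean of 9.50 above 9.44 and 9.37 in mutant p53 replicates 2 and 3.

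Lists of macrophage and adipocyte genes were shifted down with mutant p53 and wild-type mdm2, with overlap between groups in both lists. The Fc receptor gene Fcgr3 was 6.74 ± 0.05 (SD, n = 3) in p53-null and 5.98 ± 0.17 (SD, n = 3) in mutant p53 thymi, and C1qc, Cd68 and Adgre1 differed by -0.32, -0.28 and -0.35. The list of macrophages and dendritic cells had a median of -0.20 (camera adjusted p = 0.000176, limma; adjusted p = 0.978 with an estimated correlation), and the call was lost without p53-null, mdm2 wild-type replicate 2 (0.331). The adipocyte list, with Retn at -0.92, Cidec at -0.89, Lpl at -0.56 and Pparg at -0.42, had a median of -0.20 (adjusted p = 0.00613; adjusted p = 0.978 with an estimated correlation). That call was lost without p53-null, mdm2 wild-type replicate 1 (0.637) and with the Y-linked covariate (0.71). As that covariate mostly marks the same sample, these are not 2 separate checks. In the macrophage, adipocyte, replication and mitosis lists 0 genes were called over all genes and 0 adjusted over the list alone.

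No single gene passed between mutant p53 and p53-null thymi with wild-type mdm2. Prag1 was 5.79 ± 0.13 (SD, n = 3) and 7.10 ± 0.32 (SD, n = 3; adjusted p = 0.464, limma with Benjamini-Hochberg adjustment). Eri2 differed by -0.78, Rab27a by 0.58, Slc30a4 by -0.55, Wdr25 by 0.44, Cd209a by -1.07, Grin2c by 0.42, St6galnac3 by 0.77, Tlr13 by -0.63 and Cd244a by -0.71 (adjusted p = 1 each). Of the p53 targets Cdkn1a differed by -0.29 (SE 0.19), Gtse1 by 0.50, Sesn2 by 0.35 and Sulf2 by -0.29, and the list median was 0.00 (camera adjusted p = 0.96), with 0 called over all genes and 0 adjusted over the list alone. The limma test called 0 of 23332 features, and the plain linear model called 0. At an unadjusted p under 0.05 there were 690, fewer than the 1167 that chance gives. The count was 1 without p53-null, mdm2 wild-type replicate 3 and 1 in a fit to these 2 groups alone.

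Without mdm2, lists of erythroid, thymocyte and glucocorticoid-responsive genes were shifted down in mutant p53 against p53-null thymi, with overlap between groups in each list. Erythroid means were 5.063 and 5.045 in mutant p53 thymi, against 6.118 and 5.051 in p53-null thymi. Glucocorticoid response means were 8.38 and 8.175 against 8.253 and 8.803. The heme synthesis gene Alas2 was 6.44 ± 0.08 (SD, n = 2) in p53-null and 5.34 ± 0.08 (SD, n = 2) in mutant p53 thymi, and Slc4a1, Rhd and Kel differed by -1.39, -0.90 and -0.52. All 11 erythroid genes had a negative change, with a median of -0.39 (camera adjusted p = 4.96e-05, limma; adjusted p = 0.643 with an estimated correlation). Without p53-null, mdm2-null replicate 1 the call was lost and the shift turned upward (0.771). The glucocorticoid response list had a median of -0.26 (adjusted p = 0.00391; adjusted p = 0.643 with an estimated correlation), with Pik3ip1 at -0.55, Il7r at -0.44, the receptor gene Nr3c1 at -0.37 and Per1 at -0.36. TCR signalling and selection, with Pdcd1 at -0.50, Bcl2l11 and Egr2 at -0.44 and Nr4a2 at -0.38, had a median of -0.15 (adjusted p = 0.00391; adjusted p = 0.643 with an estimated correlation). Double positive thymocytes, with Ets2 at -0.30, Cd4 at -0.28, Rag2 at -0.26 and Rmnd5a at -0.20, had a median of -0.13 (adjusted p = 0.00462; adjusted p = 0.643 with an estimated correlation), and the immediate early and heat shock list, with Hsph1 at -1.02, Dnaja1 at -0.94, Ier2 at -0.34 and Ier3 at 0.33, one of -0.09 (adjusted p = 0.0289; adjusted p = 0.643 with an estimated correlation).

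Lists of muscle, stromal and Myc-related genes were shifted up in the mutant without mdm2, with overlap between groups for stromal genes. The skeletal muscle list had a median of 0.13 (camera adjusted p = 0.0113, limma; adjusted p = 0.643 with an estimated correlation), with Mb at 0.78, Pvalb at 0.60, Tnni2 at 0.43 and Tnnt3 at 0.12. Fibroblast and vessel genes had a median of 0.12 (adjusted p = 0.0117; adjusted p = 0.747 with an estimated correlation), with Pdgfra at 0.42, Col1a2 at 0.39, Tek at 0.34 and Tie1 at 0.19. The Notch and Myc programme had one of 0.10 (adjusted p = 0.0205; adjusted p = 0.643 with an estimated correlation), with Dtx4 at 0.39, Heyl at 0.37, Myc at 0.33 and Notch3 at 0.16. In the 8 lists called without mdm2, 0 genes were called over all genes, and adjusted over the list alone 1 erythroid gene and 0 others.

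Each of these 8 calls rested on single samples of 2 per group. Without p53-null, mdm2-null replicate 2 the limma camera adjusted p was 0.683 for glucocorticoid response, 0.899 for double positive thymocytes, 0.769 for fibroblasts and vessels, 0.222 for the Notch and Myc programme, 0.431 for immediate early and heat shock and 0.0868 for skeletal muscle. Without replicate 1 of that group it was 0.771 for erythroid cells, 0.306 for TCR signalling and selection and 0.0518 for skeletal muscle. Without mutant p53, mdm2-null replicate 2 it was 0.159 for glucocorticoid response, 0.612 for TCR signalling and selection, 0.912 for skeletal muscle and 0.953 for immediate early and heat shock. Without replicate 1 of that group it was 0.443 for fibroblasts and vessels and for the Notch and Myc programme. Without the dimmer 25% of features immediate early and heat shock was lost too (0.0607).

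No gene passed between p53 genotypes without mdm2. The chemokine gene Cxcl5 was 3.87 ± 0.17 (SD, n = 2) in p53-null and 4.86 ± 0.26 (SD, n = 2) in mutant p53 thymi (adjusted p = 1, limma with Benjamini-Hochberg adjustment). Serpinb11 differed by 1.27, Wfdc2 by 1.16, Olfr494 by 0.60, Adpgk by -1.06, Olfr902 by -0.55, Stmn2 by 0.54, Sema7a by -0.67 and the kinase inhibitor gene Cdkn2b by 0.55. Cdkn1a differed by 0.14 (SE 0.23), Btg2 by -0.30, Ddit4l by 0.56, Trp53inp1 by -0.26 and Tnfrsf10b by 0.28, and the p53 target list had a median of -0.05 (camera adjusted p = 0.486) with 0 called over all genes and 0 adjusted over the list alone. The limma test called 0 features, with 902 at an unadjusted p under 0.05, where chance gives 1167, and the plain linear model called 0. The count was 5 or 4 without p53-null, mdm2-null replicate 1 or 2.

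The difference of the p53 effect between mdm2 backgrounds asked whether the mutant acts differently once mdm2 is gone. Alas2 was 4.70 ± 0.14 (SD, n = 3) in p53-null and 5.37 ± 0.47 (SD, n = 3) in mutant p53 thymi with mdm2, the opposite order to that without mdm2, and the difference of effects was -1.77 (SE 0.33, adjusted p = 0.995, limma with Benjamini-Hochberg adjustment). Prag1 at -1.31, Rab27a at -0.86, Serpinb11 at 1.56, Olfr1314 at 0.89, Eri2 at 0.97, Cxcl5 at 1.14, Adpgk at -1.38, the integrin gene Itgb3 at -0.85 and Dcstamp at 1.09 did not pass either (adjusted p = 0.995 each). Cdkn1a differed by 0.42 (SE 0.30), Gtse1 by -0.69, Ddit4l by 0.88, Btg2 by -0.36 and Bbc3 by -0.58, and the p53 target list had a median of -0.08 (camera adjusted p = 0.434), with 0 called over all genes and 0 adjusted over the list alone. The limma test called 0 features, with 997 at an unadjusted p under 0.05, where chance gives 1167, and the plain linear model called 0. The count was 1 without p53-null, mdm2 wild-type replicate 3, and 2 or 1 without p53-null, mdm2-null replicate 1 or 2. Across 23332 features the p53 effects in both backgrounds had r = -0.154, with the same sign in 43.5%. The correlation rested on single samples, at -0.0131 without mutant p53, mdm2-null replicate 1, -0.0197 without p53-null, mdm2-null replicate 2 and -0.0842 without p53-null, mdm2 wild-type replicate 1.

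Camera called 6 lists for this difference. Erythroid cells, with Car2 at -1.25, Slc4a1 at -1.38 and Kel at -0.57, had a median of -0.50 (adjusted p = 0.000313, limma; adjusted p = 0.672 with an estimated correlation), lost without p53-null, mdm2-null replicate 1 (0.785). Macrophages and dendritic cells, with Siglech at 0.91, Adgre1 at 0.66, and C1qc and Ccl22 at 0.42, had one of 0.31 (adjusted p = 0.00219; adjusted p = 0.672 with an estimated correlation), lost without mutant p53, mdm2-null replicate 1 (0.258), p53-null, mdm2-null replicate 2 (0.16) or p53-null, mdm2 wild-type replicate 2 (0.0792). Glucocorticoid response, with Ddit4 at -1.94, Tsc22d3 at -1.42, Pik3ip1 at -0.73 and Cd163 at 0.66, had one of -0.27 (adjusted p = 0.041; adjusted p = 0.672 with an estimated correlation). It was lost without mutant p53, mdm2-null replicate 2 (0.354), mutant p53, mdm2 wild-type replicate 3 (0.0707), p53-null, mdm2-null replicate 2 (0.481) or p53-null, mdm2 wild-type replicate 1 (0.25). Fibroblasts and vessels, with Acta2 at 0.79, Pdgfra at 0.57, Col5a1 at 0.34 and Tek at 0.29, had one of 0.17 (adjusted p = 0.041; adjusted p = 0.672 with an estimated correlation), lost without replicate 1 of either mutant p53 group (0.322 for mdm2 null, 0.264 for wild type) or replicate 2 of either p53-null group (0.578 for mdm2 null, 0.369 for wild type).

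The other list calls on the difference were on thymocyte genes. TCR signalling and selection, with Egr2 at -0.66, Pdcd1 at -0.63, Itm2a at -0.62 and Nr4a2 at -0.57, had a median of -0.11 (camera adjusted p = 0.041, limma; adjusted p = 0.672 with an estimated correlation). It was lost without mutant p53, mdm2-null replicate 2 (0.797), mutant p53, mdm2 wild-type replicate 2 (0.179), p53-null, mdm2-null replicate 1 (0.359) or p53-null, mdm2 wild-type replicate 1 (0.104) or 3 (0.176). Mature single positive thymocytes, with Cd40lg at -0.61, Gimap3 at -0.57, Gimap4 at -0.50 and Zbtb7b at -0.38, had a median of -0.15 (adjusted p = 0.041; adjusted p = 0.672 with an estimated correlation). It was lost without mutant p53, mdm2-null replicate 2 (0.397), mutant p53, mdm2 wild-type replicate 2 (0.0524) or 3 (0.118), p53-null, mdm2-null replicate 1 (0.939, turned upward) or p53-null, mdm2 wild-type replicate 1 (0.263) or 2 (0.0792). Over all genes 0 members of the 6 lists were called, and adjusted over the list alone 1 erythroid gene and 0 others.

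Of these 6 calls only those on erythroid cells and on macrophages and dendritic cells held under each change of normalization, filter or covariate. Quantile normalization ended the calls on fibroblasts and vessels, glucocorticoid response and TCR signalling and selection (camera adjusted p = 0.0617 each, limma) and on mature single positive thymocytes (0.0642). The Y-linked covariate ended them at 0.0623, 0.204, 0.0757 and 0.204. Without the dimmer 25% of features glucocorticoid response (0.0847), TCR signalling and selection (0.0847) and mature single positive thymocytes (0.093) were lost, and the last 2 also with the liver covariate (0.0534 and 0.108).

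Over both mdm2 backgrounds, lists of replication and mitosis genes were shifted up slightly in mutant p53 thymi, with overlap between groups. This comparison includes the samples with wild-type mdm2. In mutant p53, mdm2-null replicate 2 the G2 and M mean was 9.12, below the 9.15 to 9.50 of p53-null thymi. Its G1/S mean of 8.92 lay below 9.08 in p53-null, mdm2 wild-type replicate 3 and 9.04 in p53-null, mdm2-null replicate 2. Rfc4 was 9.14 ± 0.20 (SD, n = 5) in p53-null and 9.40 ± 0.11 (SD, n = 5) in mutant p53 thymi, and Chaf1b, Cdc6 and Fen1 differed by 0.18, 0.20 and 0.26. The list of G1/S and DNA replication had a median of 0.13, positive in 25 of 26 genes (camera adjusted p = 2.6e-08, limma; adjusted p = 0.745 with an estimated correlation). The list of G2 and M phase, with Ndc80 at 0.30, Prc1 at 0.22, Nuf2 at 0.20 and Tpx2 at 0.19, had a median of 0.10, positive in 26 of 27 genes (adjusted p = 1.83e-06; adjusted p = 0.745 with an estimated correlation). Both calls held without any 1 sample, with 0 genes called over all genes and 0 adjusted over the list alone. In thymi without mdm2 the lists were not called, with medians of 0.09 (adjusted p = 0.125) and 0.04 (adjusted p = 0.395).

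No gene passed for the p53 effect over both backgrounds. The ribosomal protein gene Rpl37 was 6.47 ± 0.23 (SD, n = 5) and 7.0 ± 0.32 (SD, n = 5; adjusted p = 1, limma with Benjamini-Hochberg adjustment). Zgrf1 differed by 0.33, Mup3 by 0.34, Olfr902 by -0.37, Fam228b by 0.33, the helicase gene Wrn by -0.61, Slc30a4 by -0.41, Sqor by -0.66, Olfr1350 by -0.43 and Sfi1 by 0.26 (adjusted p = 1 each). Mdm2 differed by 0.08 and Cdkn1a by -0.12 (SE 0.15), and Tnfrsf10b, Sesn2, Gtse1 and Sulf2 by 0.22, 0.18, 0.22 and -0.13. The p53 target list had a median of -0.01 (camera adjusted p = 0.807), with 0 called over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 593 features, fewer than the 1167 that chance gives. The limma test called 0 features and the plain linear model called 0, as did limma without any 1 sample.

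Smaller list shifts with mutant p53 over both backgrounds were each lost without several samples. Adipocytes, with Cidec at -0.73, Pparg at -0.33, Lpl at -0.27 and Lep at -0.13, had a median of -0.27 (camera adjusted p = 0.00468, limma; adjusted p = 0.745 with an estimated correlation). The call was lost without replicate 1 of mutant p53, mdm2-null (0.686), p53-null, mdm2-null (0.164) or p53-null, mdm2 wild-type thymi (0.272), and with the Y-linked covariate (0.373). The Notch and Myc programme, with Dtx1 at 0.19, Myc at 0.14, Polr1b at 0.13 and Nop58 at 0.11, had a median of 0.06 (adjusted p = 0.0235; adjusted p = 0.733 with an estimated correlation). That call was lost without mutant p53, mdm2-null replicate 1 (0.28), mutant p53, mdm2 wild-type replicate 3 (0.0642) or p53-null, mdm2-null replicate 2 (0.162). Skeletal muscle, with Actn3 at 0.35, Mb at 0.30, Acta1 at 0.28 and Pvalb at 0.21, had a median of 0.06 (adjusted p = 0.0303; adjusted p = 0.745 with an estimated correlation). It was lost without replicate 2 of mutant p53, mdm2-null (0.468), mutant p53, mdm2 wild-type (0.083) or p53-null, mdm2-null thymi (0.162), or replicate 1 of the last group (0.0569), and without the dimmer 25% of features (0.072).

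Lists of thymocyte, glucocorticoid and macrophage genes were shifted down in the fit over both backgrounds, but not in each background. With mdm2 the median was 0.00 in double positive thymocytes, 0.04 in glucocorticoid response and -0.02 in TCR signalling and selection, where camera's direction was up, and without mdm2 it was 0.10 in macrophages and dendritic cells. Double positive thymocytes, with Ccr4 at -0.22, Rag2 at -0.15, Arpp21 at -0.10 and Rmnd5a at -0.08, had a median of -0.05 (camera adjusted p = 0.0366, limma; adjusted p = 0.745 with an estimated correlation). Glucocorticoid response, with Il7r at -0.34, Per1 at -0.20, Mt1 at -0.16 and Nr3c1 at -0.12, had a median of -0.08 (adjusted p = 0.049; adjusted p = 0.745 with an estimated correlation). Macrophages and dendritic cells, with Fcgr3 at -0.58, Cd68 at -0.16, Vcam1 at -0.15 and Clec9a at 0.33, had a median of -0.09 and TCR signalling and selection, with Bcl2l11 at -0.28, Egr1 and Nr4a3 at -0.12 and Nfatc1 at -0.10, one of -0.07 (adjusted p = 0.049 each; adjusted p = 0.745 with an estimated correlation). Without mutant p53, mdm2-null replicate 2 the 4 calls were lost at adjusted p of 0.144 for double positive thymocytes, 0.441 for glucocorticoid response, 0.285 for macrophages and dendritic cells and 0.728 for TCR signalling and selection. Double positive thymocytes and glucocorticoid response were also lost without mutant p53, mdm2-null replicate 1 (0.225 and 0.141), p53-null, mdm2-null replicate 2 (0.863 for both, the latter turned upward), mutant p53, mdm2 wild-type replicate 2 (0.0631 for both) or p53-null, mdm2 wild-type replicate 3 (0.145 and 0.182), and the latter without replicate 2 of that group (0.0867). Macrophages and dendritic cells were also lost without p53-null, mdm2-null replicate 1 (0.12), mutant p53, mdm2 wild-type replicate 1, 2 or 3 (0.128, 0.0631 and 0.395) or p53-null, mdm2 wild-type replicate 2 or 3 (0.923, turned upward, and 0.11). TCR signalling and selection was also lost without p53-null, mdm2-null replicate 1 or 2 (0.507 and 0.06), mutant p53, mdm2 wild-type replicate 1 or 3 (0.0805 and 0.161) or p53-null, mdm2 wild-type replicate 2 (0.262). Without the dimmer 25% of features double positive thymocytes were lost (0.073), and with the liver covariate macrophages and dendritic cells (0.0986) and TCR signalling and selection (0.11). Over all genes 0 members of the 7 smaller lists were called, and 0 adjusted over the list alone.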

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

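The tests of liver RNA, expression by thymic epithelium, an effect of mdm2 on liver genes, dilution from thymocyte genes and separate handling were chosen after the results they measure were seen. The other tests below were set before their own results were seen, although those on the liver list use genes chosen after Alb had been seen.

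Of 2 lists written after Alb had been seen, the liver list held 48 measured genes and a list of genes restricted to other organs held 40. Of the liver genes 2 lay above the median feature in mdm2 wild-type thymi, and 3 of the others, while 0 of either were in a list fixed earlier. Over both p53 genotypes the liver list had a median change of 1.72, and limma with Benjamini-Hochberg adjustment called 26 of its genes higher over all genes and 47 when adjusted within the list. Its shift had camera adjusted p = 6.39e-34, adjusted p = 0.0973 with an estimated correlation and fry adjusted p = 0.00508. The highest mean log2 signals of these genes in mdm2-null thymi, which do not rank amounts of transcript, were Alb at 11.1, Ttr at 8.87, Inmt at 8.69, Apoa2 at 8.52, Ahsg at 8.40 and Hpx at 8.21.

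Liver genes were higher in mdm2-null thymi, whose liver scores of 4.88 to 6.91 lay above the 4.02 to 4.26 of mdm2 wild-type thymi. Expression by thymic epithelium of genes of many organs was argued against, as the genes restricted to other organs had a median of -0.0636, with quartiles of -0.125 and 0.0399, and 0 of 40 were called higher. Liver RNA in the samples may explain the pattern, since the excess of liver genes over mdm2 wild-type thymi correlated between each pair of mdm2-null samples, from 0.858 to 0.944 across genes. With separate controls for the 2 samples the range was 0.823 to 0.954, against -0.608 to 0.719 between mdm2 wild-type samples. An effect of mdm2 genotype on liver genes could give the same correlation and stays open too, because 0 mdm2-null samples had a liver score within the mdm2 wild-type range.

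Features outside the liver list also rose, and 444 features fell. As a set, 432 of the rises did not follow the liver excess of the mdm2-null samples in proportion. Their median slope on it was 0.172 of that of 26 liver features (95% bootstrap interval 0.14 to 0.202, 2000 draws). The draws were of features, so the interval leaves out spread between samples. These features were picked by a test that favours an even excess, whereas the liver excess ranged from 0.169 to 1.88 of its mean. A low slope was thus partly to be anticipated. Liver RNA as their source stays open, also because they include genes that liver expresses, such as Rbp4, Hp and Orm1. Dilution of thymic transcripts by RNA of another tissue would lower thymocyte genes too. The features that fell had a median of -0.57. The 57 thymocyte genes above the median level had a median of -0.126, with quartiles of -0.229 and -0.00115. As the features that fell were picked for their falls, a smaller median in genes not so picked was to be anticipated. This comparison therefore cannot decide on dilution, which stays open. The test set beforehand, in which a fraction of 0.617 of the falls stayed called after median centring, decided nothing, as its value lay between the bounds set for it and centring shifts all features alike. RNA of fat, a change in thymic cell types and an effect of mdm2 on thymic genes stay open, as each allows the higher adipocyte list (median 0.85) and the lower double positive thymocyte list (median -0.15).

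Between mdm2 genotypes 902 features were called. Chance was argued against as the source of this number, since of 100 splits of the samples within p53 genotype 1, the real one, gave as many. The highest of the others gave 5. With 100 splits in all, chance is not excluded. A trend on gene length and signal level was argued against as the whole cause, since a fraction of 0.756 of the called features with 1 symbol and a gene length (413 of 546) stayed called after it was taken out. That fraction lay only just above the bound set for it beforehand, and a part of this trend in the calls that were lost stays open. Chromosome segments bred along with the null allele may add calls, as 7 of 100 measured neighbours of Mdm2 in assembly GRCm38.p6 were called. That share was 1.95 times that of other genes (95% interval of the odds ratio 0.788 to 4.37, Fisher's exact p = 0.0946, two-sided), which leaves this open. Separate handling or breeding of the mdm2 genotypes cannot be told apart from mdm2 loss, because 0 array name prefixes held both.

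Splits of the samples were also counted for mutant p53. With wild-type mdm2 the real comparison called 0 features and the highest other split 2, and over both mdm2 backgrounds they called 0 and 7. With a real count of 0, all 10 and all 60 splits give at least as many by construction, so neither number says anything about chance, and 10 splits are also too few for such a test.

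Single thymi lay apart from the other samples of their mdm2 genotype in 7 of 50 tests with Dixon's ratio, where chance gives about 1 in 20, or 2.5. In p53-null, mdm2-null replicate 1 the mean of the erythroid genes was 6.12 against 5.04 to 5.06 in the other mdm2-null thymi (ratio 0.983). In p53-null, mdm2-null replicate 2 the double positive thymocyte genes averaged 10.4 against 10.1 (0.846), and in mutant p53, mdm2-null replicate 2 the skeletal muscle genes averaged 5.93 against 5.52 to 5.58 (0.856). In p53-null, mdm2 wild-type replicate 1 adipocyte genes averaged 6.61 against 5.47 to 5.72 (0.779), glucocorticoid response genes 8.36 against 8.53 to 8.61 (0.656), and the Y-linked genes Kdm5d and Eif2s3y 3.59 against 9.25 to 9.35 (0.982). In p53-null, mdm2 wild-type replicate 2 early thymocyte genes averaged 6.57 against 6.42 to 6.47 (0.675). No biological explanation was tested for these samples. The labels give no sex, and only p53-null, mdm2 wild-type replicate 1 had low Y-linked signal, so sex may be unbalanced between groups.

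By camera with a preset correlation, the effect of mutant p53 on 6 gene lists differed between mdm2 backgrounds, but each had adjusted p = 0.672 with an estimated correlation and was lost without at least 1 sample. This difference cannot be told apart from the array set, since the mdm2-null groups differed in array name prefix. The median change in erythroid genes was 0.04 with mdm2 and -0.39 without it (adjusted p = 0.000313, limma), and in macrophages and dendritic cells -0.20 and 0.10 (0.00219). It was 0.10 and -0.06 in mature single positive thymocytes (0.041), -0.02 and -0.15 in TCR signalling and selection (0.041), 0.04 and -0.26 in the glucocorticoid response (0.041) and -0.01 and 0.12 in fibroblasts and vessels (0.041). The erythroid difference was lost without p53-null, mdm2-null replicate 1 (0.785), the sample with the high erythroid mean.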

How the results depend on the processing

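The liver covariate, leaving liver genes out of the counts and the averaged contrast were chosen after seeing the data. The liver score did not overlap between mdm2 genotypes, so fits with it can hardly separate liver signal from mdm2 loss. Where leaving out a sample left a group with 1, that lone sample was assumed to vary like the other groups. Precision was limited by the number of samples. The fit to 2 groups alone was not possible for results that use all 4.

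Counts for the p53 effect with mdm2, without mdm2, over both backgrounds and for the difference were 0 under each alternative, except for 1 with wild-type mdm2 in a fit to 2 groups and the fits leaving out 1 sample. Those ranged from 0 to 1 with wild-type mdm2, 0 to 5 without mdm2, 0 to 2 for the difference and 0 to 0 over both backgrounds. For mdm2 loss in p53-null thymi the 5 calls became 13 without the dimmer 50%, 2 with the liver covariate, 0 in a fit to 2 groups and 3 to 62 without 1 sample. In mutant p53 thymi the 3 calls became 7 with quantile normalization, 11 and 143 without the dimmer 25% and 50%, 25 with 1 feature per gene, 26 with trend and robust settings, 13 with array weights, 7 with the Y-linked covariate, 263 at an adjusted p under 0.10, 1 with the liver covariate, 8 in a fit to 2 groups and 0 to 63 without 1 sample. Over both p53 genotypes the 902 calls became 453 in the plain linear model (372 shared), 2141 at an adjusted p under 0.10, 461 with at least 1.5-fold change, 8 with the liver covariate (4 shared) and 114 to 776 without 1 sample. Looser or stricter thresholds change counts by construction, and for the other settings the cause was not tested.

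Of the 21 lists camera called 4, 8, 6, 3, 7, 9 and 5 in the order p53 effect with mdm2, without mdm2, their difference, mdm2 loss in p53-null, in mutant p53, p53 effect over both and mdm2 loss over both. With an estimated correlation and with fry each became 0. For the difference there were 2 with quantile normalization, 3 without the dimmer 25% and 2 with the Y-linked covariate, and for mdm2 loss over both there were 3 without the dimmer 25%. With the liver covariate there were 8 for mdm2 loss in p53-null thymi (7 higher and 1 lower, 2 shared) against 2 higher and 1 lower before, and 8 over both (7 higher and 1 lower, 2 shared) against 1 higher and 4 lower. In mutant p53 thymi there were 10 (7 higher and 3 lower, 3 shared) against 2 higher and 5 lower. Without 1 sample the ranges were 3 to 7, 8 to 11, 3 to 10, 3 to 5, 2 to 10, 4 to 10 and 2 to 7. The correlation of p53 effects between backgrounds ranged from -0.217 to -0.0131 and that of mdm2 effects from 0.318 to 0.538. The cause was not tested.

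The fall of Mdm2 kept its direction throughout, and over both p53 genotypes it kept its call in all 22 alternatives, at -1.25 to -1.15. In p53-null thymi it was -1.23 with the liver covariate and -1.17 in a fit to 2 groups, both no longer called (adjusted p = 0.137 and 0.223, limma). Without 1 sample it was -1.23 to -1.11, and the call was lost without p53-null, mdm2 wild-type replicate 2 (0.065). In mutant p53 thymi it was -1.27 and -1.21 there, also not called (adjusted p = 0.145 and 0.0953, limma). Without 1 sample it was -1.25 to -1.17, and the call was lost without either mutant p53, mdm2-null sample (0.0528 and 0.0689) or any mutant p53, mdm2 wild-type sample (0.0582 to 0.0878). The cause was not tested. Of 282 results on named genes 35 were called, 3 of which kept the call in each alternative, and 24 uncalled ones were called in some. With the liver covariate 3 changed sign: Uox to -0.17, Fgg to -0.23 and Fgb to -0.0072, as the covariate takes out the liver signal itself. Another 17 uncalled ones changed sign in some alternative.

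Samples with the same replicate number did not deviate together (13 pairs, r from -0.19 to 0.19, 1 over 0.1), so the numbers do not pair them. The replicate block gave 5 calls in mutant p53 thymi and 61 over both p53 genotypes (59 shared), and the fall of Mdm2 was -1.15 and -1.19 in p53-null and mutant p53 thymi, not called (adjusted p = 0.139 and 0.073, limma). The block also ended the list call on mature single positive thymocytes for mdm2 loss in mutant p53 thymi (camera adjusted p = 0.103, limma). For the difference of the p53 effect it called 7 lists (6 shared).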

Other observations

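The genes named in this part were chosen after the result was seen.

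Outside the liver list, the haptoglobin gene Hp rose by 2.01 over both p53 genotypes without mdm2 (SE 0.37, adjusted p = 0.0271, limma with Benjamini-Hochberg adjustment), the orosomucoid gene Orm1 by 1.70 (SE 0.28, adjusted p = 0.0222), Pon1 by 2.15 (SE 0.37, adjusted p = 0.0235) and Fbp1 by 1.72 (SE 0.33, adjusted p = 0.0308). Agtrap, which had the lowest adjusted p in both single comparisons of mdm2 genotype, rose by 1.63 (SE 0.07, adjusted p = 1.19e-05). No list or source was tested for these genes as a group.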
